A study of Homo sapiens with 2 samples.

How the data were processed

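RNA abundance was measured in LNCaP cells, an androgen-responsive human prostate carcinoma line, with Affymetrix Human Genome U133 Plus 2.0 arrays. The control culture had received lentivirus made from the empty pLKO.1 vector, and the knockdown culture had received lentivirus carrying a short hairpin RNA against KDM4A. Per the labels' protocols, cells were harvested 3 days after infection, total RNA was extracted with Trizol and 3 µg was turned into biotinylated cRNA. Each group had 1 array, so no test over replicates, no p-value and no left-out replicate could be had.

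The authors deposited log2-scale values, and the submitters' processing notes name RMA (robust multi-array averaging) without a version. The file holds 44672 probe sets. In every row the values of the 2 arrays summed to 0 within 1e-06, so each value is a probe set's signal minus the mean of the 2 arrays. The columns were therefore mirror images, with a correlation of -1 over probe sets and medians of -0.0072 (control) and 0.0072 (knockdown). Signal levels, background and detection are lost by this centring, and no filter on dim probe sets was possible. The log base, the centring step and any filter on probe sets before deposit are not given in the sources used here; the base was taken as 2 because RMA works on that scale, and every fold below rests on it. The direction was taken from the sample each column belongs to.

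The difference of a probe set was the knockdown value minus the control value. Genes were named through the platform annotation, with symbols checked by Entrez identifier against a table of RefSeq genes of GRCh38.p14, which matched 34839 of 34880 probe sets with 1 gene and changed no symbol. Another 1619 probe sets named several genes and 8131 were unnamed here, and these entered no gene value. The 42 AFFX control probe sets were kept apart. A gene's difference was the mean over its probe sets, which gave 17689 genes, 8745 of them with 1 probe set. Before the data were examined, the plan had been to use each gene's brightest probe set, to keep the brighter probe sets and to match random lists on mean signal. Centring ruled these out, so the mean over probe sets and no filter, listed in advance as other settings and needing no level, became the main setting, and random lists were matched on the number of probe sets per gene (1, 2, 3, or 4 and more).

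Genes were called higher or lower by a fixed rule of size, 2-fold or more, which is not a test. The only error that 2 arrays allow is the spread between probe sets of a gene, given as ± SD with the number of probe sets. It covers probe noise and transcript isoforms, not the spread between cultures. For 31 gene lists fixed before the data were examined, the median difference was set against the medians of 10000 random lists of the same size. A list stood apart when its median lay under the 2.5th or over the 97.5th percentile, which chance alone would give for 1.55 of 31 lists. This describes the 2 arrays only, and genes of a list are not independent. The lists held 690 different genes, of which 600 were measured. They covered KDM4 and other histone demethylases, replication, mitosis, pyruvate dehydrogenase, glycolysis, the TCA cycle, oxidative phosphorylation, androgen response, p53, apoptosis, interferon, stress responses, lipid synthesis, hypoxia, inflammation, heat shock, immediate early genes, ribosomes, metallothioneins, neuroendocrine and mesenchymal genes, reference genes, and markers of luminal, basal, stromal, blood and embryonic kidney cells.

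Named genes followed a rule fixed in the same way. It took 11 genes whatever their values (the 4 KDM4 genes, E2F1, the 4 PDK genes, PDHA1 and PDHB), the 12 largest differences each way among genes at least 2-fold apart whose probe sets all lay on the same side of 0, and up to 4 members of each list with the largest differences. On differences simulated from the spread between probe sets for all 17689 genes, the 2-fold rule found 6% of 50 genes changed 1.5-fold, 54% of 50 changed 2-fold and 100% of 50 changed 3-fold. It also called 0.663% of 17489 unchanged genes. In 200 random lists of 30 genes, 4.5% fell outside the percentile bounds, and 100% of 50 lists shifted by -0.3 fell under the lower bound. These lists were drawn at random from the same gene values as the lists they were set against. They check the calculation only, not how often lists of genes that vary together fall outside the bounds.

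The alternatives were leaving out probe sets ending in _x_at or _s_at, which can match several transcripts, subtracting the median difference, size rules of 1.5-fold and 3-fold, list means and unmatched random lists. Chosen after seeing the data were the median over probe sets, genes with 2 or more probe sets alone, and 2 stricter rules on the agreement of probe sets. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. No genome build is named for the array values, so no coordinates are given.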

Results

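Gene expression was profiled in LNCaP prostate carcinoma cells 3 days after infection with a lentivirus carrying either the empty pLKO.1 vector or a hairpin against KDM4A, a demethylase of histone H3 lysine 9 and lysine 36. The question was which transcripts differ when KDM4A is reduced. There was 1 array in each group, so no value below has a replicate check, and the number of arrays limits the precision. Each value is the log2 difference, knockdown minus control, of values the authors normalised with RMA and centred on the mean of the 2 arrays. An error given as ± SD is the spread between probe sets of a gene on these arrays, not between cultures. Over all 44672 probe sets the median difference was 0.014, with quartiles of -0.18 and 0.20. The 18 probe sets for hybridisation spike-ins, bacterial and phage transcripts meant to be added in equal amounts, differed by -0.0099 ± 0.045 (SD, n = 18 probe sets), and the 7 for bacterial poly-A spike-ins by 0.078 ± 0.18 (SD, n = 7 probe sets). The 3' minus 5' contrast, a sign of RNA integrity, moved by -0.12 for ACTB and by -0.097 for GAPDH.

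KDM4A was lower in the knockdown by 2.26-fold (log2 difference -1.18 ± 0.40, SD over 2 probe sets). Its probe sets read -0.90 and -1.46. Of its paralogs, KDM4C lay at -0.42 ± 0.44 over 3 probe sets, KDM4B at -0.026 ± 0.36 over 8 and KDM4D at 0.15 ± 0.12 over 2, and none of these reached 2-fold. The median of the 4 KDM4 genes, -0.23, lay at the 6.06th percentile of random lists. It was -0.089 (20.4th percentile) with medians over probe sets, and the list mean was -0.37 (2.98th percentile). This list includes KDM4A, the target of the hairpin, so its position is partly set by the knockdown itself. Among 16 other histone lysine demethylases, none differed 2-fold and the list median of 0.11 lay at the 91.3rd percentile, with a mean of 0.023 at the 58.5th. The members farthest from 0 were JMJD1C (-0.60 ± 0.43, 5 probe sets), KDM2B (-0.59), KDM1B (0.55 ± 0.028, 2 probe sets) and KDM3A (0.44).

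Among 17689 genes, 205 were at least 2-fold higher and 255 at least 2-fold lower in the knockdown, which is 1.16% and 1.44% of genes. In the simulation from probe set spread alone, 0.663% of 17489 unchanged genes passed the same rule. That share counts both directions together, whereas 1.16% and 1.44% are for each direction alone. Of the genes called, 125 of the higher and 115 of the lower genes rest on a single probe set. Where there were 2 or more probe sets, all lay on the same side of 0 for 78 of 80 higher and 124 of 140 lower genes. The call rests on the mean of these same probe sets, so such agreement is largely built in. Over all 8944 genes with 2 or more probe sets, all lay on the same side for 50.3%, against 33.8% expected by chance. The pooled SD between probe sets of a gene was 0.33 on the log2 scale. When genes were picked by their first probe set alone, 227 were at least 2-fold lower, and the mean of the remaining probe sets lay below 0 for 197 of them, with a median of -0.67, and was itself at least 2-fold lower for 67. Of 117 genes picked as at least 2-fold higher, the mean of the remaining probe sets lay above 0 for 110, with a median of 0.80, and was at least 2-fold higher for 45.

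Genes of mitosis were lower in the knockdown as a group. All 42 measured genes of the mitosis and G2/M list lay below 0, 29 of them by 2-fold or more, and the list median was -1.42, a 2.68-fold lower level. DLGAP5, a spindle assembly protein, was 18.3-fold lower (-4.20). TOP2A, the topoisomerase that untangles chromosomes, was 11.5-fold lower (-3.53 ± 0.19, 2 probe sets). NDC80 and NUF2, partners in the kinetochore complex that binds microtubules, were 10.9-fold and 9.66-fold lower (-3.44 and -3.27). The list median lay below those of all 10000 random lists, the lowest of which was -0.18. Of 19 list members with 2 or more probe sets, 17 (89.5%) had all of them below 0. If each probe set fell on either side independently, 17.3% would. Every gene of the list had a mean below 0, so such agreement is largely built in.

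Replication genes and E2F targets were also lower, by a smaller amount. Of 51 measured genes, 46 lay below 0, 10 were at least 2-fold lower and none was 2-fold higher, with a list median of -0.37 and a mean of -0.56. RRM2, a subunit of the reductase that makes deoxynucleotides, was 5.86-fold lower (-2.55 ± 0.80, 2 probe sets). CDC6, a loader of the replicative helicase, was 3.37-fold lower (-1.75 ± 0.54, 2 probe sets). POLE2, a subunit of DNA polymerase epsilon, lay at -1.68 and PRIM1, the primase subunit, at -1.49. E2F1 itself lay at -0.30 ± 0.040 over 2 probe sets, short of 2-fold. The lowest of 10000 random lists had a median of -0.15. Together the mitosis and replication lists held 39 of the 255 genes that were at least 2-fold lower.

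**Figure D1:**
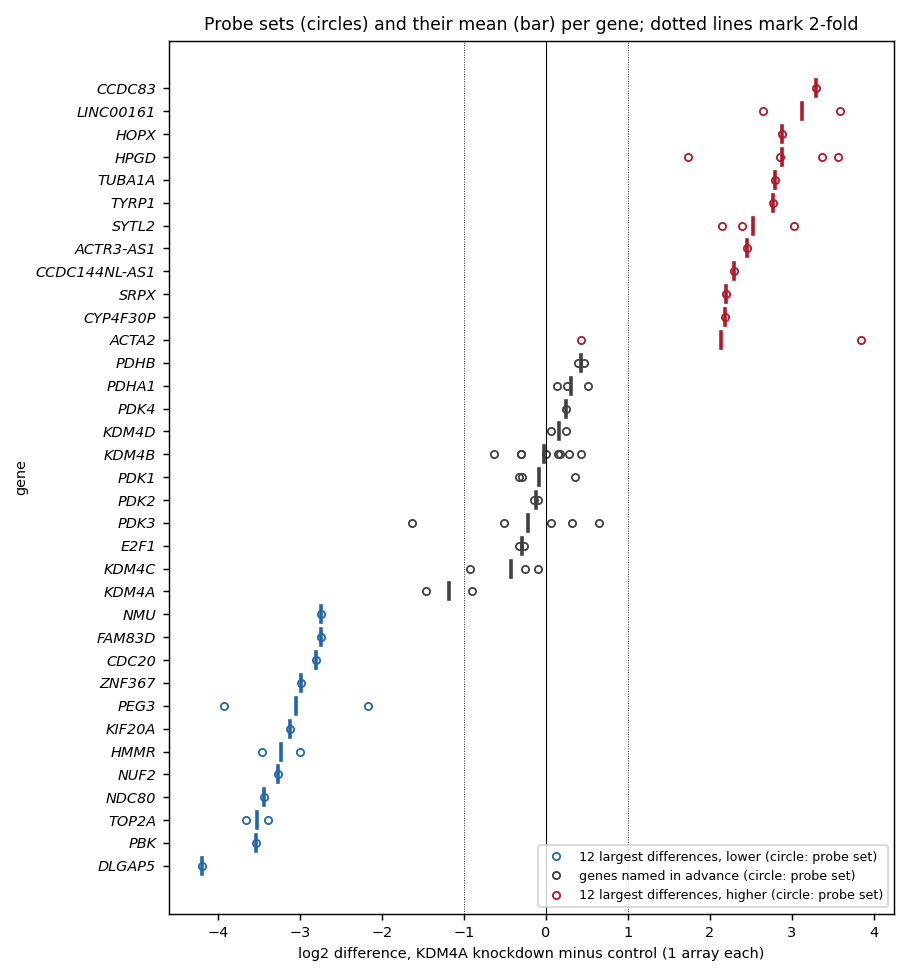
Log2 difference (knockdown minus control, x axis) of each probe set (circles) and of their mean (bars) for the genes named in advance and the 12 largest differences each way (y axis), from 1 array per group. KDM4A lies at -1.18, the 12 lowest genes between -4.20 and -2.74 and the 12 highest between 2.14 and 3.29, and the ACTA2 and PDK3 probe sets lie far apart.

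Genes of the pyruvate dehydrogenase complex and its regulators, which set the entry of pyruvate into mitochondrial oxidation, did not stand apart. None of 11 measured members reached 2-fold, and the list median of 0.11 lay at the 85.2nd percentile; it was 0.18 without probe sets that can match several transcripts and 0.0058 among genes with 2 or more probe sets. PDHB and PDHA1, subunits of the decarboxylase, lay at 0.43 ± 0.052 (2 probe sets) and 0.30 ± 0.19 (3 probe sets), and PDHX, which anchors the E3 component, at 0.36. The kinases that inhibit the complex lay at -0.086 ± 0.39 for PDK1 (3 probe sets), -0.12 ± 0.030 for PDK2 (2 probe sets), -0.22 ± 0.89 for PDK3 (5 probe sets) and 0.25 for PDK4. The probe sets of PDK1 ran from -0.33 to 0.36 and those of PDK3 from -1.63 to 0.65, so neither gene has a settled direction on these arrays.

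Glycolytic genes lay slightly above 0, with 19 of 22 measured members above it, none 2-fold higher and a median of 0.25. The largest differences were those of PFKFB4 (0.98 ± 0.31, 2 probe sets) and PFKFB3 (0.52), which make the activator of phosphofructokinase, HK1 (0.75), the first enzyme of the pathway, and ENO2 (0.54). The median lay above all 10000 random lists, but was 0.16, at the 95.4th percentile, without probe sets that can match several transcripts and 0.15, at the 95.95th, among genes with 2 or more probe sets, which ends the call. TCA cycle genes (median 0.11, 18 measured, 92.0th percentile) and nuclear genes of oxidative phosphorylation (median 0.0095, 46 measured, 38.4th percentile) did not stand apart, and none of them differed 2-fold. MDH2 lay at 0.68 ± 0.64 over 2 probe sets, ACO1 at 0.52 ± 0.17 over 2, SDHD at -0.43 and MDH1 at 0.35. NDUFS1, of complex I, lay at -0.61 ± 0.56 over 4 probe sets and ATP5MC3, of the ATP synthase, at 0.41 ± 0.37 over 3. COX5B lay at -0.37 ± 0.16 over 4 and NDUFB10 at -0.36 ± 0.0086 over 2.

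Genes of cholesterol synthesis were higher in the knockdown. Of 18 measured members, 16 lay above 0 and 5 were at least 2-fold higher, with a median of 0.51 (1.42-fold) that exceeded all 10000 random lists. Without probe sets that can match several transcripts the median was 0.30 over 13 genes, at the 99.86th percentile, which kept the call. HMGCS1, which makes the precursor of mevalonate, was 2.97-fold higher (1.57 ± 0.41, 2 probe sets). MSMO1, a sterol methyl oxidase, was 2.90-fold higher (1.54), INSIG1, the sterol sensor that retains SREBP in the endoplasmic reticulum, 2.16-fold (1.11 ± 0.16, 3 probe sets) and STARD4, a sterol carrier, 2.13-fold (1.09). Fatty acid synthesis genes had a median of 0.34, with 11 of 15 above 0 and 1 at least 2-fold higher. That gene was ELOVL6, a fatty acid elongase (1.18 ± 0.37, 3 probe sets), followed by ACSL4 (0.94), ACSS2 (0.71) and ACSL1 (0.61 ± 0.22, 2 probe sets). This second list exceeded all random lists, but lay at the 87.5th percentile, with a median of 0.12, without probe sets that can match several transcripts.

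Targets of p53, a tumour suppressor that LNCaP cells retain in wild-type form, were higher. Of 29 measured members, 25 lay above 0, 4 were at least 2-fold higher and none was 2-fold lower, with a median of 0.35 above all 10000 random lists. CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was 3.81-fold higher (1.93). FAS, a death receptor, was 3.71-fold higher (1.89 ± 0.69, 5 probe sets), TP53I3 2.56-fold (1.35) and TIGAR, a fructose bisphosphatase, 2.32-fold (1.22). The apoptosis regulators did not stand apart (median 0.080, 25 measured, 88.4th percentile). BIK, a BH3-only protein, was the only one of them to reach 2-fold (1.37). BAX lay at 0.59 ± 0.026 and PMAIP1 at 0.53 ± 0.23, each over 2 probe sets, and CFLAR at -0.52 ± 0.41 over 12.

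The unfolded protein and integrated stress response list was lower, with 23 of 33 members below 0, 5 at least 2-fold lower and a median of -0.23 below all 10000 random lists (mean -0.38). The members with the largest differences went both ways. ASNS, asparagine synthetase, was 3.21-fold lower (-1.68), SLC7A11, the cystine transporter, 3.17-fold (-1.66 ± 0.51, 3 probe sets) and TRIB3, a pseudokinase induced by ATF4, 2.57-fold (-1.36 ± 0.023, 2 probe sets). VLDLR, a lipoprotein receptor, was 2.34-fold higher (1.22).

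Androgen-induced genes had a median of 0.32 above all 10000 random lists, but members lay on either side. Of 25 measured, 18 lay above 0 and 2 were at least 2-fold higher. HPGD, which inactivates prostaglandins, was 7.34-fold higher (2.88 ± 0.82, 4 probe sets) and BMPR1B, a BMP receptor, 2.29-fold (1.20 ± 0.67, 3 probe sets). FKBP5 lay at 0.79 ± 0.051 over 3 probe sets, while TMPRSS2 lay at -0.76 ± 0.16 over 4. Androgen-repressed genes also lay above 0 (median 0.25, 8 of 9 members, 98.5th percentile), with CDK8 at 0.87 ± 0.12 over 3 probe sets, SESN1 at 0.56, FOLH1 at 0.48 and DDC at 0.30 ± 0.20 over 2. This call ended among the 6 genes left without probe sets that can match several transcripts and among the 4 genes with 2 or more probe sets, where the median was 0.27 in both, at the upper bound itself and at the 95.02nd percentile.

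Markers of the luminal prostate cell did not stand apart (median 0.11, 10 measured, 83.3rd percentile). KRT19 (1.35 ± 2.02) and FOXA1 (-1.16 ± 1.75) passed 2-fold only through 1 of 2 probe sets each, and the other read -0.075 and 0.079. CDH1 lay at 0.59 ± 0.38 over 2 probe sets and KRT8 at 0.41. Nor did markers of basal epithelium (median -0.074, 6 measured; KRT14 at 0.41, ITGA6 at -0.22 ± 0.37, KRT5 at -0.22), leukocytes (0.013, 8 measured; CD3D at 0.24, NKG7 at -0.14) or the embryonic kidney line from which packaging cells derive (0.022, 8 measured; NEFL at 0.49 ± 0.22, PAX2 at -0.34 ± 0.26). The basal median was -0.20 over 5 genes without probe sets that can match several transcripts (5.19th percentile), still inside the bounds. Markers of fibroblasts and smooth muscle had a median of 0.060 over 11 genes (70.6th percentile), 0.20 among the 8 with 2 or more probe sets (97.3rd percentile), and a mean of 0.29 at the 99.5th, with ACTA2 at 2.14 ± 2.42 over 2 probe sets, COL1A1 at 0.73 ± 0.76 over 4 and COL3A1 at 0.63 ± 0.68 over 3. Of the 11 genes, 4 lay below 0, the lowest being FAP at -0.29.

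**Figure D2:**
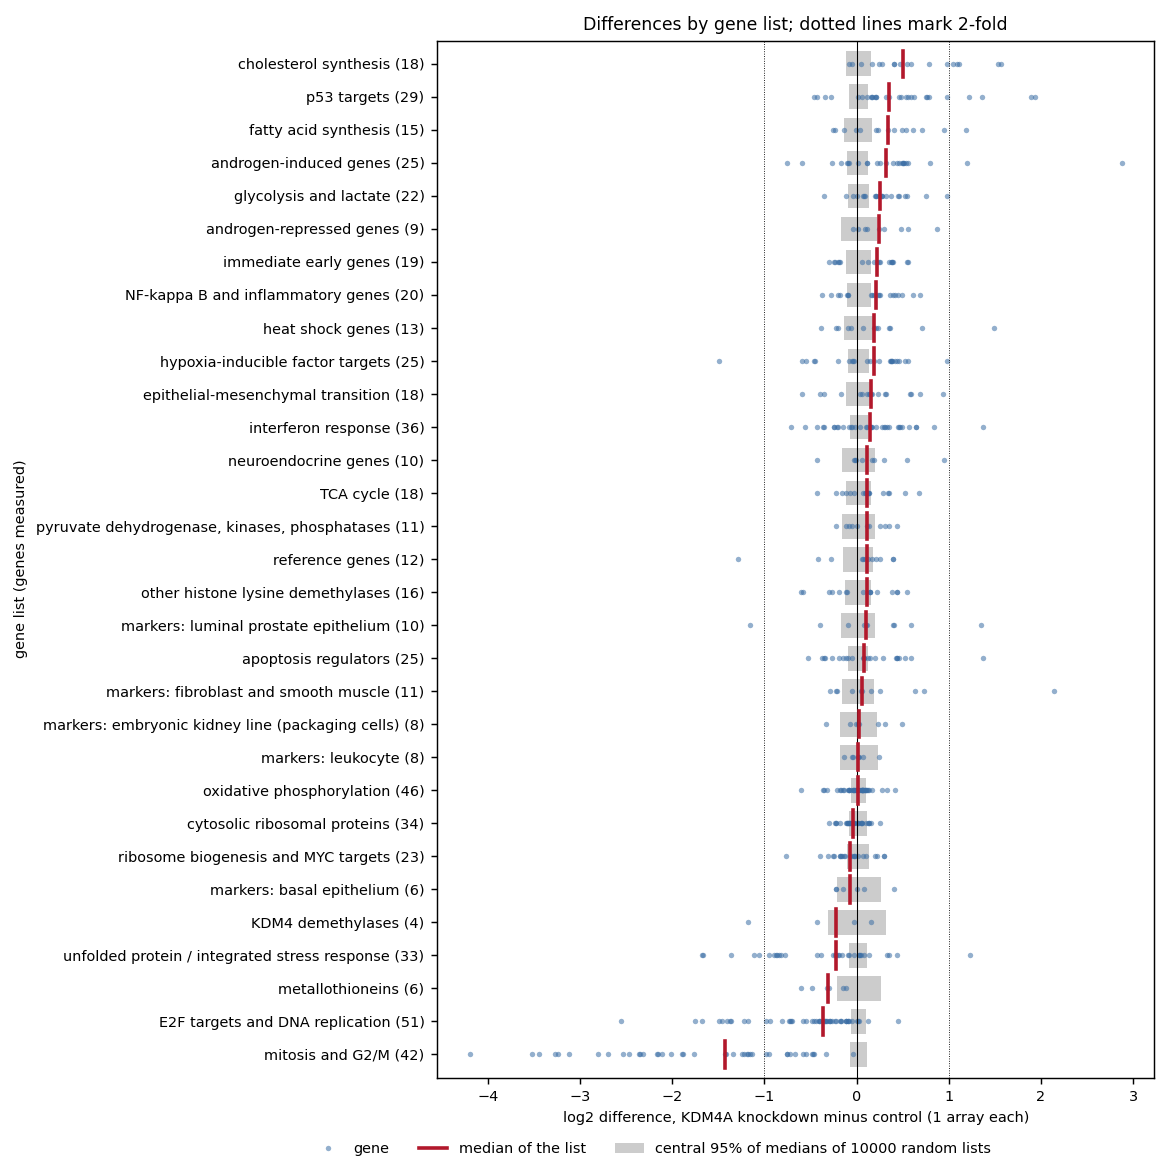
Log2 difference (knockdown minus control, x axis) of every measured gene (points) in 31 gene lists fixed in advance (y axis, number of genes in brackets), from 1 array per group; red bars are list medians and grey bars the central 95% of medians of 10000 random lists matched on the number of probe sets. The mitosis median lies at -1.42 and the cholesterol synthesis median at 0.51, outside the grey bars, and oxidative phosphorylation lies at 0.0095, inside.

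Several lists lay higher by small amounts, in calls that did not hold under every setting. The interferon response (median 0.15, 36 measured, 99.4th percentile) had 1 gene at least 2-fold higher, TRIM22 (1.37), with IFIT1 at 0.84, IFIT3 at 0.64 ± 0.37 over 2 probe sets and DDX60 at -0.71; its mean lay at the 96.7th percentile. Hypoxia-inducible factor targets (median 0.19, 25 measured, 99.7th percentile) included LOX, a collagen cross-linking enzyme 2.81-fold lower (-1.49 ± 0.081, 2 probe sets), besides PFKFB4, NDRG1 (-0.59) and ADM (0.55), and their mean of 0.080 lay at the 82.2nd percentile. NF-kappa B and inflammatory genes (median 0.21, 20 measured, 99.7th percentile) had no member 2-fold apart; SOD2 lay at 0.69, NFKBIE at 0.61 and CXCL8 at 0.49 ± 0.28 over 2 probe sets, and the mean lay at the 95.8th percentile. Immediate early genes (median 0.22, 19 measured, 99.7th percentile) likewise had none, with ZFP36 at 0.55, KLF6 at 0.55 ± 0.29 over 5 probe sets and a mean of 0.14 at the 94.4th percentile. Heat shock genes had a median of 0.19 over 13 genes (98.3rd percentile) that turned to -0.19 over 9 genes without probe sets that can match several transcripts. HSPA4L was their only member to reach 2-fold (1.49 ± 0.24, 2 probe sets), with HSPB1 at 0.71 and HSPD1 at -0.38 ± 0.96 over 5 probe sets. Metallothioneins lay lower (median -0.31, all 6 measured members below 0, 0.75th percentile), led by MT2A (-0.61) and MT1H (-0.49). Their probe sets can share near-identical sequence, and the list lay at the 4.66th percentile among genes with 2 or more probe sets.

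Cytosolic ribosomal proteins (median -0.040, 34 measured, percentile 11.2), ribosome biogenesis and MYC targets (-0.074, 23 measured, percentile 6.71), neuroendocrine genes (0.11, 10 measured, 85.2nd percentile), epithelial-mesenchymal transition genes (0.15, 18 measured, 96.8th percentile) and reference genes (0.11, 12 measured, 88.2nd percentile) did not stand apart. The neuroendocrine mean was 0.17 and the reference gene mean -0.018, neither outside the bounds. The members farthest from 0 were RPS24 (-0.30 ± 0.52, 2 probe sets), ODC1 (-0.77), SCG5 (0.95), ITGA5 (0.94) and TFRC, the transferrin receptor, which was 2.44-fold lower (-1.29 ± 0.80, 4 probe sets). ACTB, often used as a reference, lay at -0.41 ± 0.037 over 3 probe sets.

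Of the 12 largest lower differences, DLGAP5, TOP2A, NDC80, NUF2, HMMR (-3.24 ± 0.33, 2 probe sets), KIF20A (-3.13) and CDC20 (-2.80) were in the mitosis list. The others were PBK, a mitotic kinase (-3.54), PEG3, an imprinted zinc finger gene (-3.05 ± 1.25, 2 probe sets), ZNF367 (-2.98), FAM83D, a spindle protein (-2.74), and NMU, a neuropeptide (-2.74). PEG3 overlaps an antisense gene, PEG3-AS1, which lay at -2.10. The largest higher differences were those of CCDC83 (3.29), LINC00161 (3.12 ± 0.66, 2 probe sets), HOPX, a homeodomain protein (2.88), HPGD, the tubulin gene TUBA1A (2.80), TYRP1, a melanosomal enzyme (2.77), and SYTL2, a vesicle protein (2.53 ± 0.45, 3 probe sets). ACTR3-AS1 (2.46), CCDC144NL-AS1 (2.29), SRPX (2.20), CYP4F30P (2.19) and ACTA2 (2.14 ± 2.42) followed. Of these 24 genes, 9 of the lower and 8 of the higher rest on a single probe set, and ACTA2 overlaps FAS in the RefSeq annotation.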

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

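The tests in this part were chosen after the differences had been seen. Probe sets with no gene name here entered no comparison, yet 61 of 8131 were at least 2-fold higher and 194 at least 2-fold lower in the knockdown array. That is 0.75% and 2.39%, against 1.48% and 2.39% of probe sets with 1 gene. The lowest of them read -2.87 and -2.84, and the highest 2.65 and 2.46. These signals lie outside the gene comparisons, which is why they are listed, and no explanation was tested.

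The lower mitosis genes are the pattern with the largest size. A scaling error of a whole array would move all classes alike, but the ribosomal protein median lay 1.38 above the mitosis median. The values were already normalised, with a median difference of 0.014 over all probe sets, so this contrast could not have shown a whole-array shift. Dilution of LNCaP cells by non-dividing cells of another type would lower luminal markers with the mitosis genes, but the luminal median lay 1.53 above the mitosis median. An effect of this hairpin or this culture other than loss of KDM4A cannot be told apart from an effect of KDM4A, since there was 1 array per group and no second hairpin. Fewer dividing cells after KDM4A loss therefore stays an untested candidate explanation.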

How the results depend on the processing

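No paired analysis was possible because each group has 1 array, and for the same reason no replicate could be left out. The planned brightest-probe-set, 50th and 70th percentile filter and loess settings were not run because the values hold no signal level, and their alternatives, the mean over probe sets and no filter, were the main setting. Settings with 2 or more probe sets, the median over probe sets and rules on probe set agreement were chosen after seeing the data. The counts of 205 higher and 255 lower genes became 760 and 774 with a 1.5-fold rule and 45 and 81 with a 3-fold rule. Among genes with 2 or more probe sets alone they were 80 and 140, and 37 and 51 where every probe set of such a gene passed 2-fold; fewer genes were eligible there. The 11 lists over the upper bound became 6 without probe sets that can match several transcripts and 5 among genes with 2 or more probe sets. The mitosis median of -1.42 became -1.48 and -1.15 under these settings and -1.70 as a mean, and the replication median of -0.37 became -0.56 as a mean. The glycolysis median of 0.25 became 0.16 without such probe sets and 0.15 with 2 or more, the pyruvate dehydrogenase median of 0.11 became 0.18 without such probe sets (96.07th percentile) and 0.0058 with 2 or more (42.1st percentile), and the androgen-induced median of 0.32 became 0.25 with medians over probe sets. The heat shock median reversed from 0.19 to -0.19 without such probe sets. The cause of these moves was not tested. The mitosis, replication and stress response lists stayed under the lower bound in all 5 settings that could change a list call, and the cholesterol, p53 and androgen-induced lists over the upper bound. Of the values of the counts and main lists, with the changed size rules and median subtraction included, 51 stayed the same, 18 moved and 0 reversed. Of the values of single genes and the other lists, with median subtraction left out, 381 stayed within their spread, 22 moved beyond it and 1 reversed. Subtracting the median difference of 0.014 moves a list and its random lists alike, so it could change no list call and is not counted as a check of them. Random lists could not be matched on signal, so a list of strongly expressed genes is set against lists that include silent ones.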

Other observations

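Besides the lists fixed in advance, 6 lists were written after the main differences had been seen; the tests on histones and endoplasmic reticulum chaperones are descriptions only, and the others were predicted before their own values were looked at. Genes of clustered histones were higher in the knockdown. Of 37 measured, 26 lay above 0, 15 were at least 1.5-fold and 4 at least 2-fold higher, and none was 1.5-fold lower, with a median of 0.39 above all 10000 random lists (highest 0.25). H2AC8 was 3.46-fold higher (1.79), H2BC21 2.62-fold (1.39) and H2BC4 2.19-fold (1.13). Copies of these genes are nearly identical, so single members are uncertain, and most of their transcripts lack a poly-A tail in dividing cells.

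Transcripts for amino acid supply were lower. A list of aminoacyl-tRNA synthetases, amino acid transporters and serine and proline enzymes had all 21 measured members below 0, 6 of them by 2-fold or more, with a median of -0.69 against a lowest random median of -0.23. GARS1, glycyl-tRNA synthetase, was 3.93-fold lower (-1.97), SARS1 2.56-fold (-1.35), the glutamine transporter SLC1A5 2.21-fold (-1.15) and MTHFD2, a mitochondrial folate enzyme, 2.05-fold (-1.03). The endoplasmic reticulum chaperones of the stress response list had a median of 0.031 over 13 genes, at the 57.0th percentile. Of these, 8 lay above 0, the highest being HSP90B1 (0.44), HSPA5 (0.35) and MANF (0.33), and 0 were 1.5-fold higher. The other 5 lay below 0, and 2 were at least 1.5-fold lower, DNAJB9 (-0.82 ± 0.054, 3 probe sets) and DNAJC3 (-0.78 ± 0.62, 4 probe sets). Below 0 lay 23 of all 33 stress response genes but only 5 of these 13 chaperones, so the genes outside the chaperone list lay mostly below 0. Single genes among them were picked after their values were seen and not tested as a group. ATF6 lay at -0.95 ± 0.83 (4 probe sets), HERPUD1 at -0.38 ± 0.19 (2 probe sets), XBP1 at -0.26 ± 0.35 (2 probe sets) and EDEM1 at -0.19, while PPP1R15A lay at 0.14 ± 0.31 (2 probe sets). The hypothesis was that the lower stress response list may reflect a lower amino acid response rather than lower endoplasmic reticulum stress. The amino acid supply list was written after the stress response list, with ASNS at -1.68, had been seen to be lower on the same 2 arrays. Its median of -0.69 goes with the first part of the hypothesis only, and adds no independent support for it. Lower endoplasmic reticulum stress stays open, and the difference between the lists was not tested.

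Condensin, cohesin and centromere genes outside the mitosis list were also lower as a group. Their median was predicted to lie under the 2.5th percentile of random lists, and it did. The prediction was written after the mitosis genes had been seen to be lower on the same 2 arrays, so it adds no independent support. Of 25 measured, 21 lay below 0 and 8 were at least 2-fold lower, with a median of -0.42 under the 2.5th percentile of random lists (-0.091). NCAPG, a condensin subunit, was 4.10-fold lower (-2.03), SGO2 2.90-fold (-1.54) and HJURP, the CENP-A chaperone, 2.74-fold (-1.45), while NCAPD3 was higher (0.78). Of the cohesin genes, STAG2 lay at -1.19, but SMC1A (-0.24), SMC3 (-0.23), STAG1 (-0.14) and RAD21 (-0.045) lay nearer 0.

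KDM4A acts on a repressive histone mark that also covers zinc finger gene clusters, and lower zinc finger transcripts were predicted. The median of 195 zinc finger genes on chromosome 19 was -0.016, at the 2.88th percentile, so the prediction was not met at the 2.5th percentile, with 1 gene at least 2-fold higher and 1 at least 2-fold lower. Melanoma antigen genes had a median of -0.16 over 10 genes, at the 1.99th percentile, and MAGEA1 (-1.29), MAGEA12 (-1.23) and MAGEA6 (-1.16) were at least 2-fold lower; some of these genes are near-identical copies, and the list lies close to the bound.

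Probe sets of 70 genes lay 2 or more apart on the log2 scale, with PRR11 (4.08), YME1L1 (3.42) and ACTA2 (3.42) at the top. Transcripts of a neighbouring gene could be read by such probe sets. An adjacent gene at least 2-fold apart in the direction of the extreme probe set was present for 5.71% of them (exact 95% interval 1.58% to 14.0%) and for 2.92% of the others. Shares less than 2-fold apart had been set beforehand to count against this explanation, and these shares were. The interval is wide and covers 2.92%, so too few genes were left to decide.

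Genes that differed lay next to each other in 16 adjacent pairs, both at least 2-fold the same way, against a median of 6 and a central 95% of 2 to 12 in 1000 shuffles of gene positions within chromosomes. The prediction for chance placement, a number inside that range, was not met, and 1 shuffle of 1000 gave as many. The stricter bound set for excluding chance, a number above every shuffle, was not met either. Without overlapping genes 11 pairs remained, at the upper end of the central 95% of shuffles (11), and 32 of 1000 shuffles gave as many, so overlapping genes are a possible explanation for part of the excess. The pairs included SYTL2 (2.53) with CCDC83 (3.29), FOXM1 (-2.11) with RHNO1 (-1.68), and ACTA2 (2.14) with FAS (1.89).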
